A study of Homo sapiens with 6 samples.

How the data were processed

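Total RNA of HCT-8 cells was measured on 6 single-colour Affymetrix arrays, 3 labelled TRIB3-shRNA and 3 labelled Control-shRNA. Per the labels' protocols, RNA was extracted with Trizol and 5.5 µg of single-stranded cDNA was fragmented and labelled with biotin. The deposited log2 values had been made with RMA in Affymetrix Expression Console 1.4.1, per the submitters' processing notes. RMA corrects background, normalizes arrays by quantiles and summarises probes. The log2 scale was read from the values, and the genome build is not given in the sources used here. Scanner files were not used here, so background correction and probe summary could not be varied. Groups and replicate numbers were taken from sample titles. Another label field ends alike for all samples of a group, so the labels leave open whether the numbers stand for cultures, repeat arrays or different hairpins. In the last case the SD, the replicate block and the comparison of same-numbered arrays would include differences between hairpins. The highest share of features with identical values in any pair of arrays was 0.127%, so no pair was treated as a repeat of the same array.

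The table held 53617 features. Of these, 16098 were paired with 1 gene symbol, 0 with several and 37519 with none in the annotation used here. Symbols were checked through gene identifiers against a RefSeq gene table of assembly GRCh38.p14, and all 16098 matched. That table was used only for names, biotypes, spans (the length of the gene on the genome) and gene order, and no coordinates are given because the build behind the array annotation was not stated. For the 779 genes with more than 1 feature the brightest over all 6 arrays was kept, which left 14884 genes. Array medians over these genes ran from 5.62 to 5.70 and SDs from 1.90 to 2.00.

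The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided) on the deposited values without renormalization or a filter on dim features. Calls were made at a Benjamini-Hochberg adjusted p of 0.05, and a second count asked for at least 2-fold. The values were log2 as the design assumed. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Of 33 lists fixed before the data were examined, 30 had at least 5 measured genes. The lists of drug efflux transporters, mitochondrially encoded genes and replication-dependent histones had 0 genes named in the annotation used and were not analysed here. Several lists share members.

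The rule for named genes was also fixed before the data were examined. It took TRIB3 and the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher mean lay above the median of all genes. It added up to 3 called members of each list with the smallest adjusted p, and a fixed set of Wnt, stem cell and Tribbles genes whatever their p. Small RNA genes and uncharacterised loci were not named. Genes named outside the rule are marked as such.

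Alternatives fixed before the data were examined were the replicate number as a block, leaving out each array, quantile normalization, centring on the median or the 75th percentile, filters at the 25th and 50th percentile of mean signal, an intensity trend, robust fitting, array weights, the mean of a gene's features and all features without collapsing. A test against a fold of 1.2 and an adjusted p of 0.01 were added for the count of genes. Leaving out both arrays numbered 3, removing each array's trend against gene span (lowess with a span of 0.3) and leaving out a chromosome 7 run were chosen after seeing the data.

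Runs of neighbouring genes were searched with Python 3.11.15 and numpy 2.4.6 on fold changes with the span trend removed, against 200 shuffled gene orders. For the test of that trend the search was also run on every other gene without its removal. The steps were tested on simulated data made for the same comparison of 14884 genes, 200 of them changed. The limma test recovered 0% of changes of 0.5 on the log2 scale, 71.5% of changes of 1 and 96.5% of changes of 2, with 0, 8 and 13 false calls. The simulated noise was independent between genes, unlike that of the real arrays, and 1435 genes were called in the real data. These rates check the steps and do not carry over to the real comparison.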

Results

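Gene expression was measured on 6 Affymetrix arrays of HCT-8 cells, a human colon cancer line. The cells had been transfected with a plasmid for a short hairpin RNA (shRNA) against TRIB3 or with a control shRNA, and pools of resistant cells had been selected with hygromycin for 14 days, starting 24 hours after transfection, without cloning. TRIB3 encodes a pseudokinase of the Tribbles family and is itself induced by the stress factors ATF4 and CHOP. There were 3 arrays labelled TRIB3-shRNA and 3 labelled Control-shRNA, and 14884 genes were tested. Values are RMA signals on the log2 scale. The number of arrays limits the precision, and the labels do not say whether replicates were separate cultures or carried different hairpins, so the p-values measure only the spread between these samples, which may be technical. Adjusted p-values are from limma's moderated test with Benjamini-Hochberg adjustment, and all directions give the arrays labelled TRIB3-shRNA relative to those labelled Control-shRNA.

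The targeted gene was examined first, because it checks the labels. TRIB3 signal went against them: it was higher in the arrays labelled TRIB3-shRNA, at 8.40 ± 0.11 (SD, n = 3), than in the control arrays, at 7.33 ± 0.17 (SD, n = 3). The difference was 1.07 on the log2 scale (SE 0.14, 2.09-fold, limma adjusted p = 0.0041). The arrays labelled TRIB3-shRNA read 8.43, 8.48 and 8.27 and the control arrays 7.37, 7.14 and 7.48, so each of the former lay above each of the latter. The only feature of TRIB3 in the annotation was transcript cluster 16910609, and whether the hairpin's target lies in it was not analysed here. Every direction below rests on the deposited labels, which this gene does not bear out. Of its relatives, TRIB1 differed by -0.16 (adjusted p = 0.462) and TRIB2 by 0.36 (adjusted p = 0.172), and neither passed the test.

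**Figure D1:**
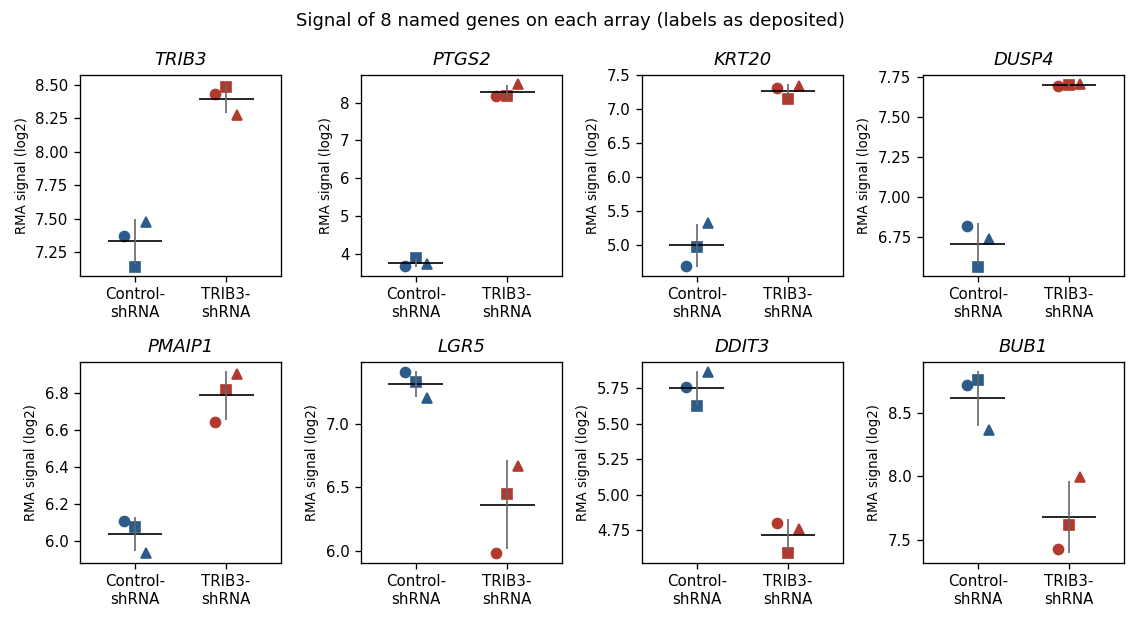
RMA signal (log2, vertical axes with separate scales that do not start at 0) of 8 named genes on the 3 arrays of each labelled group. Circles, squares and triangles are replicates 1, 2 and 3, horizontal lines are group means and vertical lines are ± 1 SD. TRIB3 was higher in all 3 arrays labelled TRIB3-shRNA (8.27 to 8.48) than in the controls (7.14 to 7.48).

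The question the design poses is which genes differ between the cells with the TRIB3 hairpin and those with the control hairpin. The arrays labelled TRIB3-shRNA had higher signal of PTGS2, the inducible cyclooxygenase, by 4.51 on the log2 scale (SE 0.14, adjusted p = 2.2e-06). They also had higher signal of KRT20, a keratin of differentiated intestinal epithelium, by 2.27 (SE 0.17, adjusted p = 0.000444) and of the cell adhesion gene CEACAM6 by 2.48 (SE 0.32, adjusted p = 0.00429). Among genes named by the rule fixed beforehand, the largest fall was that of TCEAL8, which fell by 2.82 on the log2 scale (SE 0.15, 7.04-fold, adjusted p = 9.52e-05). LGR5, a receptor that marks intestinal stem cells, fell by 0.95 on the log2 scale (SE 0.18, adjusted p = 0.0173). Its call was lost with the replicate number as a block (adjusted p = 0.0501) and, for example, without Control-shRNA replicate 1 (adjusted p = 0.0813). It was lost under 5 of its 20 alternatives, with adjusted p from 0.00282 to 0.0813.

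In all, 1435 of 14884 genes passed an adjusted p of 0.05, of which 484 were higher and 951 lower. Of these, 353 differed at least 2-fold, 67 higher and 286 lower. The 3 arrays of each group did not overlap for 1434 of the 1435 genes, which the call itself favours. Over all genes tested the share was 32.0%. Chance gives 10% on average over splits of the arrays. Genes vary together, so a single split can lie far from that average without a group effect. The share of higher calls was 33.7% on the deposited values and 50.8% after centring each array on its 75th percentile (853 higher, 825 lower). With median centring it was 44.6% (659 higher, 818 lower). Centring on the 75th percentile moved the median of all genes from 0.04 to 0.14 on the log2 scale. The count depended on which arrays were in the fit: without Control-shRNA replicate 2 it was 199, and without TRIB3-shRNA replicate 3 it was 2696. Without TRIB3-shRNA replicate 1 it was 507, without TRIB3-shRNA replicate 2 it was 372 and without Control-shRNA replicate 1 it was 261. Of 73 named genes called, TRIB3 apart, 31 kept their calls under all alternatives run and 42 lost them under at least 1. Calls were lost most often without Control-shRNA replicate 2 (40 genes) or 1 (39), without TRIB3-shRNA replicate 2 (35) or 1 (27), with the replicate number as a block (34) and over all features (33).

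The other genes among the 10 largest rises under that rule were DHX32 (3.58), HTRA1, a secreted serine protease (2.90), the long non-coding RNA LINC02582 (2.72) and TMEM45B (2.56). They were followed by PYCARD, the inflammasome adaptor (2.28), PLPP2, a lipid phosphatase (2.14), and HSD11B2, which inactivates cortisol (2.08). Their adjusted p-values were at most 0.0038. The other genes among the 10 largest falls were the transcription factor KLF7 (-2.25), TFPI, an inhibitor of coagulation (-2.24), ENPP1 (-2.16), UTRN, which encodes utrophin (-2.05), and SH3BGRL (-2.04). The list went on with the ferric reductase gene CYBRD1 (-1.95), SOCS2, a suppressor of cytokine signalling (-1.94), its antisense RNA SOCS2-AS1 (-1.92) and SKIC3 (-1.85). SKIC3 had an adjusted p of 0.0233 and lost its call under 4 of its 20 alternatives, for example without Control-shRNA replicate 2 (adjusted p = 0.104, range 0.00275 to 0.104). The lower group mean of PTGS2 (3.77), DHX32 (3.87), LINC02582 (3.00), CEACAM6 (3.22), KLF7 (3.91), TFPI (3.82) and SH3BGRL (3.69) lay below the 25th percentile of each array (4.26 to 4.36). Signal over background was not analysed here, so the size and rank of these differences are not settled. LINC02582 lies in a run of 57 neighbouring genes of chromosome 18 whose median log2 fold change, with the trend on gene span removed, was 0.31.

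Of 47 measured G2/M and mitotic genes, 8 fell, 1 rose and 38 did not pass the test, and adjusted over the list alone 20 fell and 2 rose. The list was called lower by camera with a preset correlation (adjusted p = 5.47e-05 over 30 lists), but was not called with an estimated correlation (adjusted p = 0.527) or in fry's directional test (adjusted p = 0.0597). SGO1, which protects centromere cohesion, fell by 1.34 on the log2 scale (adjusted p = 0.0204), as did CKAP2L (-1.21, adjusted p = 0.0198) and the spindle checkpoint kinase gene BUB1 (-0.94, adjusted p = 0.0174). BUB1 and CKAP2L lost their calls under 6 of 20 alternatives each (adjusted p up to 0.0878 and 0.0931) and SGO1 under 4 of 20 (up to 0.0935), in each case without TRIB3-shRNA replicate 2 and without Control-shRNA replicate 1 or 2, and for BUB1 and CKAP2L also without TRIB3-shRNA replicate 1. The member that rose was CDC20 (0.52, adjusted p = 0.0438), named after its value was seen. The list's median was -0.37. Its mean deviation was -0.39, -0.27 and 0.02 in the arrays labelled TRIB3-shRNA and 0.31, 0.28 and 0.05 in the control arrays, so that the pair numbered 3 differed little. The members that fell spanned a median of 37.3 kb of the genome and the list's other members 22.8 kb. Of the 32 measured G1/S and DNA replication genes, 3 rose and 0 fell: the phosphatase gene CDC25A (0.80), UHRF1 (0.51) and FEN1 (0.45), with a camera adjusted p of 0.314 for the list. FEN1 lost its call under 8 of 20 alternatives (adjusted p up to 0.17), UHRF1 under 6 (up to 0.139) and CDC25A under 1 (0.0511, without Control-shRNA replicate 2).

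Of 33 measured genes of the MAPK/ERK response, 8 rose, 0 fell and 25 did not pass the test, and adjusted over the list alone 10 rose. The list was called higher with the preset correlation (camera adjusted p = 0.0033), but not with an estimated correlation (adjusted p = 0.527). EREG, a ligand of the epidermal growth factor receptor, rose by 1.58 (SE 0.21, adjusted p = 0.00436). DUSP4, a phosphatase of MAP kinases, rose by 0.99 (SE 0.12, adjusted p = 0.00367), and SPRY4, an inhibitor of the pathway, by 0.81 (SE 0.12, adjusted p = 0.00637). These 2 are feedback inhibitors that the pathway induces. The list's median was 0.28. Its mean deviation was 0.19, 0.21 and 0.06 in the arrays labelled TRIB3-shRNA and -0.19, -0.23 and -0.03 in the control arrays, so that the pair numbered 3 differed little. Without TRIB3-shRNA replicate 2 the median was 0.16.

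Of 22 measured p53 targets, 5 rose, 1 fell and 16 did not pass the test, and adjusted over the list alone 9 rose and 1 fell. The count depended on the scaling: 7 rose with quantile normalization and 8 with either centring, with 1 fall in each. The list was called higher with the preset correlation (camera adjusted p = 0.0126), but not with an estimated correlation (adjusted p = 0.527). The estimated correlation of this list was -0.023, below the preset 0.01, so correlation among its members does not account for that loss. Its camera p with that correlation was 0.0239 before adjustment over the lists. In fry's directional test, which asks a different question, the list kept its call (adjusted p = 0.00282). TP53INP1 rose by 0.92 (adjusted p = 0.0139), the BH3-only gene PMAIP1 by 0.75 (adjusted p = 0.0125) and the nuclease gene AEN by 0.71 (adjusted p = 0.015). Their calls were lost under 2 of 19, 4 of 20 and 5 of 20 alternatives (adjusted p up to 0.0723, 0.0644 and 0.0804). The control mean of TP53INP1 (4.03) lay below the 25th percentile of each array, so the size of its rise is not settled. The member that fell was APAF1, by 1.23 on the log2 scale (adjusted p = 0.0241), named after its value was seen. The list's median was 0.36. Its call was also lost with array weights (adjusted p = 0.0594), without TRIB3-shRNA replicate 3 (0.074) and, in an alternative chosen after seeing the data, with both arrays numbered 3 left out (adjusted p = 0.2). Among regulators of apoptosis, 4 of 19 measured genes rose and 1 fell, with a camera adjusted p of 0.134. With quantile normalization or either centring 6 rose and 1 fell. The apoptosis list was called with quantile normalization (adjusted p = 0.0482), with only features above the median level (0.0478) and in fry's directional test (0.0297). BCL2, which opposes apoptosis, rose by 1.54 (adjusted p = 0.00365) and BOK, a relative that promotes it, by 1.38 (adjusted p = 0.00365). BCL2 and PMAIP1 lie in the chromosome 18 run.

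Of 21 measured markers of absorptive enterocytes and colonocytes, 4 rose, 1 fell and 16 did not pass the test. The list was called higher with the preset correlation (camera adjusted p = 0.0365) but not with an estimated correlation (adjusted p = 0.527), and lost its call under 8 of 21 alternatives. KRT20 and CEACAM6 led those that rose, while HPGD, which degrades prostaglandins, fell by 0.67 on the log2 scale (adjusted p = 0.0248, up to 0.116 and not called under 6 of 20 alternatives). The median was 0.25. This call was also lost with only features above the 25th percentile (adjusted p = 0.0751) or the median level (0.34) and, in alternatives chosen after seeing the data, with the span trend removed (0.0663) or both arrays numbered 3 left out (0.0755). It was also lost without TRIB3-shRNA replicate 2 (0.089), without TRIB3-shRNA replicate 3 (0.0672) and without Control-shRNA replicate 1 (0.0554). Among 24 secretory lineage markers only the Notch ligand gene DLL1 rose (1.43, adjusted p = 0.0014) and 0 fell, with a camera adjusted p of 0.314. Of 31 Notch pathway genes 2 rose, DLL1 and HEY2 (0.77), and 2 fell, among them RBPJ (-0.77), with a camera adjusted p of 0.775. HEY2 lost its call under 4 and RBPJ under 6 of 20 alternatives (adjusted p up to 0.0772 and 0.133).

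**Figure D2:**
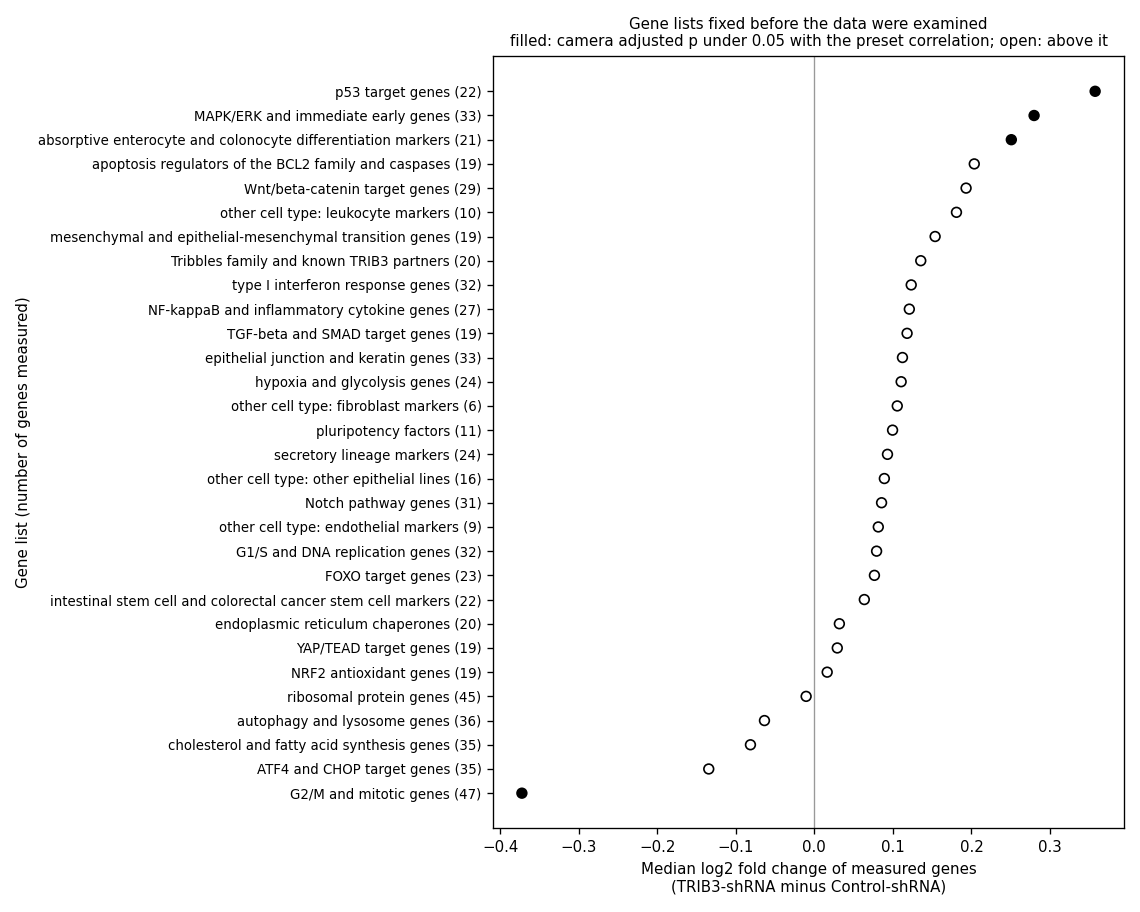
Median log2 fold change (TRIB3-shRNA minus Control-shRNA, horizontal axis) of the measured genes of each of 30 gene lists fixed before the data were examined, with the number of measured genes in parentheses. Filled points passed a camera adjusted p of 0.05 with the preset correlation. The 4 filled points are p53 targets (0.36), MAPK/ERK genes (0.28), absorptive markers (0.25) and G2/M genes (-0.37), and 0 lists passed with an estimated correlation.

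Wnt and stem cell genes moved in both directions. Of 29 measured Wnt/beta-catenin targets 6 rose and 3 fell, and adjusted over the list alone 11 rose and 4 fell, with a median of 0.19 and a camera adjusted p of 0.0737. The list was called as higher with quantile normalization (adjusted p = 0.0378), with only features above the median level (0.017), without TRIB3-shRNA replicate 1 (0.0429) and in fry's directional test (0.0221), and its adjusted p reached 0.527 with an estimated correlation. CLDN1 (0.71) and ETS2 (0.65) rose, and LGR5 fell. CLDN1, whose group means of 2.84 and 3.55 both lay below the 25th percentile of each array, lost its call under 3 of 18 alternatives (adjusted p up to 0.0625) and ETS2 under 6 of 20 (up to 0.0825). ASCL2, a transcription factor of intestinal stem cells, rose by 0.58 (adjusted p = 0.0475) and lost its call under 10 of its 20 alternatives, with adjusted p from 0.0104 to 0.179. AXIN2, a feedback target of the pathway, was 0.37 higher (adjusted p = 0.0867), and MYC (-0.04), CCND1 (-0.01), SOX9 (0.10), CD44 (0.19) and PROM1 (0.03) did not pass the test, with adjusted p from 0.617 to 0.975. Both group means of CD44 (3.14 and 3.34) lay below the 25th percentile of each array, so its value says little about a difference. Of 22 stem cell markers 4 rose and 2 fell (camera adjusted p = 0.797), with the oxidase gene NOX1 falling by 1.10 on the log2 scale and MEX3A rising by 0.62. The second feature of MEX3A differed by 0.02. CTNNB1 and TCF7L2 were not analysed here, since no feature was paired with them in the annotation used. Of 11 pluripotency factors 1 rose, KLF4 (0.64), with a camera adjusted p of 0.474. NOX1, MEX3A and KLF4 lost their calls under 1, 7 and 6 of 20 alternatives (adjusted p up to 0.0552, 0.15 and 0.141).

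Of 35 measured targets of ATF4 and CHOP, 2 rose and 4 fell, and adjusted over the list alone 2 rose and 8 fell (median -0.13, camera adjusted p = 0.134). The median was -0.05 with quantile normalization and -0.03 after centring on the 75th percentile, and fry's directional test on the deposited values called the list lower (adjusted p = 0.0367). IARS1, an aminoacyl-tRNA synthetase gene, fell 2.83-fold (adjusted p = 0.003). DDIT3, which encodes CHOP, fell by 1.03 on the log2 scale (SE 0.13, adjusted p = 0.00367), and the asparagine synthetase gene ASNS fell by 0.97 (SE 0.12, adjusted p = 0.00365). ASNS lies in a run of 371 neighbouring chromosome 7 genes whose median was -0.26, as does INSIG1. The 2 members that rose were TRIB3 and GDF15 (0.76), the latter named after its value was seen. Of 20 Tribbles family members and known partners, 2 rose and 1 fell (camera adjusted p = 0.484). Those were TRIB3, STK11 (0.68) and DDIT3. Of 20 endoplasmic reticulum chaperone genes 1 rose, WFS1 (0.87), and 1 fell, SEL1L (-0.85), with a camera adjusted p of 0.94. STK11, WFS1 and SEL1L each lost their calls under 6 of 20 alternatives (adjusted p up to 0.139, 0.0928 and 0.109).

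Genes of cholesterol and fatty acid synthesis included 5 of 35 that fell and 0 that rose (camera adjusted p = 0.178), among them STARD4 (-1.20), INSIG1 (-0.76) and ACACB (-0.68). These 3 lost their calls under 6 alternatives each (adjusted p up to 0.105, 0.108 and 0.112). The list's median was -0.08 and turned to 0.02 after centring on the 75th percentile. Of 33 epithelial junction and keratin genes 3 rose and 5 fell (camera adjusted p = 0.482), with CLDN1 higher and the desmosomal gene PKP2 at -1.02, not called under 2 of 20 alternatives (adjusted p up to 0.0629). Of that list 6 rose and 5 fell after centring on the 75th percentile, and 4 rose and 5 fell with quantile normalization or median centring. Of 19 mesenchymal genes 1 rose and 3 fell (camera adjusted p = 0.797): TNC (-1.12), SNAI2 (-0.59) and THBS1 (-0.58) fell, while the median was 0.15 and the mean -0.04. TNC kept its call under all 19 alternatives, SNAI2 lost it under 8 of 19 (adjusted p up to 0.115) and THBS1 under 6 of 20 (up to 0.121). Of 27 inflammatory genes 2 rose and 3 fell (camera adjusted p = 0.484), with PTGS2 higher and the chemokine genes CXCL8 (-0.81) and CXCL3 (-0.73) lower. The inflammatory list was called with only features above the median level (adjusted p = 0.0119), and CXCL8 and CXCL3 lost their calls under 3 and 4 of 19 alternatives (up to 0.0608 and 0.0938). The mean of CXCL8 in the arrays labelled TRIB3-shRNA (4.22) lay below the 25th percentile of each array, so the size of its fall is not settled. Of 32 type I interferon genes 0 rose and 1 fell, EIF2AK2 (-1.16), with a camera adjusted p of 0.571. Of 19 YAP/TEAD targets 4 rose and 0 fell (camera adjusted p = 0.797), among them ANXA1 (1.24) and CLU (0.53). EIF2AK2 and CLU lost their calls under 2 and 6 of 20 alternatives (adjusted p up to 0.0743 and 0.163).

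Among the remaining lists, 2 of 36 autophagy and lysosome genes rose and 3 fell (camera adjusted p = 0.314), with MCOLN1 higher (0.63) and BNIP3L (-0.98) and CALCOCO2 (-0.85) lower. Their calls were lost under 6, 4 and 5 of 20 alternatives (adjusted p up to 0.0909, 0.0851 and 0.0861). Of 19 TGF-beta targets 1 rose, SKI (0.64), and 2 fell, SKIL (-0.84) and SNAI2 (camera adjusted p = 0.484). SKI lost its call under 7 of 20 alternatives and SKIL under 6 of 19 (adjusted p up to 0.152 and 0.0803). Of 23 FOXO targets 2 rose, PMAIP1 and PIK3IP1 (0.51), and 1 fell, RBL2 (-0.84), with a camera adjusted p of 0.907. With quantile normalization 1 rose and 2 fell, while both centrings kept 2 and 1. PIK3IP1, with an adjusted p of 0.0497 and group means of 3.64 and 4.15, was not called under 12 of 18 alternatives (adjusted p up to 0.169), and RBL2 was not called under 6 of 20 (up to 0.129). Of 19 NRF2 targets 0 rose and 2 fell, MGST1 (-1.69) and GSTM3 (-0.58), with a camera adjusted p of 0.956, a median of 0.02 and a mean of -0.06. With quantile normalization and after centring on the 75th percentile 2 rose and 1 fell, and with median centring 1 rose and 2 fell. The mean of MGST1 in the arrays labelled TRIB3-shRNA (3.66) lay below the 25th percentile of each array, which leaves the size of its fall unsettled. Of 24 hypoxia and glycolysis genes 0 rose and 2 fell, BNIP3L and INSIG2 (-0.60), with a camera adjusted p of 0.94, a median of 0.11 and a mean of -0.04. GSTM3 and INSIG2 lost their calls under 8 and 6 of 20 alternatives (adjusted p up to 0.112 and 0.115). The chaperone list had a median of 0.03 and a mean of -0.03. Of 45 ribosomal protein genes 0 were called (camera adjusted p = 0.995, median -0.01, mean 0.01). Markers of fibroblasts (6 measured), leukocytes (10), endothelium (9) and other epithelial lines (16) had 0 calls, with camera adjusted p-values of 0.815, 0.484, 0.571 and 0.571.

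The 6 arrays separated by label along the first principal component, which held 61.5% of the variance. Scores were 37.46, 28.02 and 6.58 for the arrays labelled TRIB3-shRNA and -30.7, -30.85 and -10.51 for the control arrays, so both arrays numbered 3 lay between the others of the 2 groups. Pearson correlations over genes ran from 0.979 to 0.993 within groups and from 0.955 to 0.982 between them. The group difference correlated with gene span across 11916 protein-coding genes, which are not independent replicates, at a Spearman rho of -0.277. In the fifth of genes with the shortest spans 105 were called higher and 47 lower, and in the fifth with the longest 53 higher and 327 lower.

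**Figure D3:**
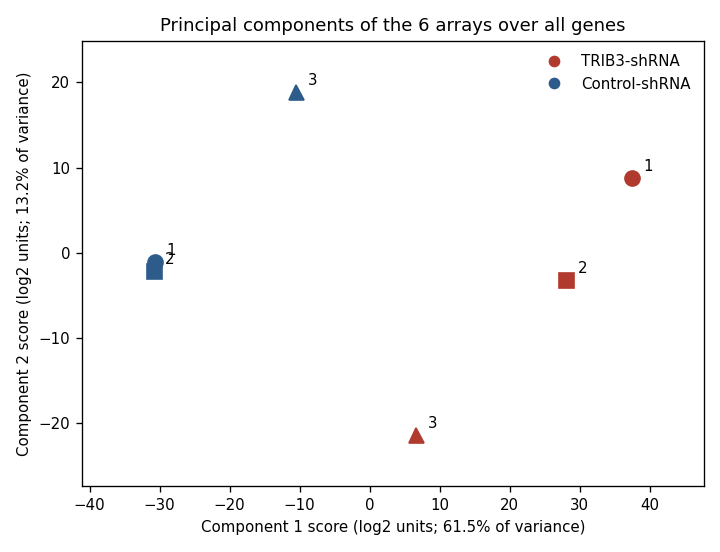
Scores of the 6 arrays on the first and second principal components over all genes (log2 units), with red for TRIB3-shRNA, blue for Control-shRNA and the replicate number beside each point. The arrays numbered 3 have first-component scores of 6.58 and -10.51, between those of the other arrays.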

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

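Features without a gene symbol, which enter the results above only through the alternative over all features, held signal that differed between the groups. In a fit of named and unnamed features together, 601 of 37519 unnamed features passed a limma adjusted p of 0.05, of which 200 were higher and 401 lower in the arrays labelled TRIB3-shRNA, and 367 differed at least 2-fold. The same fit called 440 features of named genes. No explanation was tested for these features, and TRIB3 itself goes against the labels from which their direction is read.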

How the results depend on the processing

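The settings without both arrays numbered 3, without the span trend and without the chromosome 7 run were chosen after seeing the data. TRIB3 was higher in the arrays labelled TRIB3-shRNA under all alternatives run, by at least 0.97 on the log2 scale, with adjusted p from 0.00089 to 0.0302. The count of 1435 genes was 402 with the replicate number as a block, 4099 with array weights, 3392 with both arrays numbered 3 left out, 263 against a fold of 1.2 and 228 at an adjusted p of 0.01. Leaving out each array in turn gave 199 (without Control-shRNA replicate 2) to 2696 (without TRIB3-shRNA replicate 3), with 261 without Control-shRNA replicate 1, 372 without TRIB3-shRNA replicate 2 and 507 without TRIB3-shRNA replicate 1. The count of 353 genes at least 2-fold apart was 632 with array weights, 1019 with both arrays numbered 3 left out and 145 to 715 with each array left out (TRIB3-shRNA replicates 1, 2 and 3 gave 206, 222 and 715, Control-shRNA replicates 1, 2 and 3 gave 180, 145 and 574). Over all features the unit is the feature, not the gene: 1041 passed, 440 of them of named genes, and 592 were also at least 2-fold apart, 225 of them of named genes. Of the 402 called with the block, 394 were among the 1435, in the same direction. Deviations of same-numbered arrays from their group means correlated at -0.196, -0.092 and -0.43, and 0 of 6 arrays correlated best with its own number. Both arrays numbered 3 lay toward the other group, which by itself makes these correlations negative. Whether the numbers pair the arrays therefore cannot be told. The 4 lists called became 0 with an estimated correlation, 13 with fry's directional test (10 gained, and G2/M lost at an adjusted p of 0.0597) and 28 with its mixed test, and 2 with both arrays numbered 3 left out. They were 2 without TRIB3-shRNA replicate 3 and 2 to 5 across the arrays left out. fry asks a different question from camera, since it does not set a list against other genes. Its directional test gained the lists of Wnt, apoptosis, ATF4, secretory, autophagy, G1/S, junction, mesenchymal, cholesterol and YAP/TEAD genes. Their fry adjusted p ran from 0.0221 to 0.0367. For the other changes in these counts the cause was not tested, except that fewer arrays or a stricter threshold enter by construction. G2/M and MAPK/ERK genes kept their calls under every alternative with a preset correlation, with adjusted p up to 0.00954 and 0.021. Over single named genes, 1364 results were on the same side of the threshold, 227 lost and 4 gained a call. Over lists 591 were on the same side, 15 lost and 16 gained. No result changed its direction while called. Signal over background was not analysed here.

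Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes (1435, the highest of the others 0), 1 as many genes at least 2-fold apart (353, the highest other 0) and 1 as many lists (4, the highest other 2). With 10 splits the share is never under 0.1, too few for a share under 0.05.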

Other observations

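Of 10 measured genes of the HOXB cluster, chosen after their values were seen, 6 fell in the arrays labelled TRIB3-shRNA and 0 rose, with no test of enrichment. Those that fell were HOXB3, HOXB5, HOXB6, HOXB7, HOXB8 and HOXB9, with log2 fold changes from -1.44 (HOXB5) to -0.70 (HOXB8). HOXB2 (-0.35), HOXB4 (-0.21), HOXB1 (0.18) and HOXB13 (0.20) did not pass, with adjusted p from 0.265 to 0.48. The count was also 6 under quantile normalization and both centrings. Of 7 HOXC genes 3 rose and 1 fell, and of 9 HOXD genes 1 rose and 0 fell. These genes set position along the body axis in development. The search for runs of neighbouring genes was also chosen after seeing the data. A run of 57 neighbouring genes of chromosome 18, from MALT1 to PARD6G, held 15 genes called higher and 0 called lower, and 51 of the 57 lay above 0 (permutation p = 0.00498, the smallest that 200 shuffled orders can give). It includes KDSR (1.02) and CNDP2 (1.06) beside BCL2, PMAIP1 and LINC02582.

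The tests of the 3 patterns described next, with their bounds, were all chosen after the results they bear on had been seen. Their 95% intervals are taken over genes, which vary together and are not independent replicates. Such intervals measure the spread over genes and not the uncertainty of an array or of the group difference. TRIB3 was higher, not lower, in the arrays labelled TRIB3-shRNA. An exchange of 1 array of each group is argued against, since the lowest array labelled TRIB3-shRNA lay 0.80 above the highest control array, against a pooled SD of 0.143. A rise of ATF4 targets by about that of TRIB3 is argued against too: the median of the other 34 list members was -0.14 (95% interval -0.22 to -0.03, SD of members 0.452), and the highest over quantile normalization, both centrings and members outside the runs was -0.030 (interval -0.10 to 0.07). An exchange of all labels cannot be told apart from a true rise, because all 3 arrays lay above every control array in either case. A smaller rise of ATF4 targets stays open only under the other scalings, whose intervals hold 0. On the deposited values the interval lay below 0, with 24 of the 34 members below 0 and 10 above. After centring on the 75th percentile, which gave the highest median, the median of all genes was 0.14, above that of the members. DDIT3 fell under each scaling, with changes of -0.93 or below. A response of the cells to the hairpin or to selection stays open too, untested.

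Both arrays numbered 3 lay between the others, 0.412 of the way to the controls for TRIB3-shRNA replicate 3 and 0.319 of the way in the other direction for Control-shRNA replicate 3. Mixing of RNA into Control-shRNA replicate 3 is argued against as the whole cause. Genes at least 2-fold higher in the other TRIB3-shRNA arrays gave a share of 0.123 (95% interval 0.1 to 0.181) and genes lower there 0.465 (0.454 to 0.479). The intervals of the 2 sets stayed apart at cutoffs of 1.5 (0.071 and 0.417) and 2 (0.038 and 0.303) on the log2 scale. Both shares fell as the cutoff rose. Genes were chosen on the same arrays that set the scale, so no single share is an estimate of foreign RNA. For TRIB3-shRNA replicate 3 the same shares do not decide. They were 0.291 (0.219 to 0.335) and 0.369 (0.354 to 0.383), but their intervals met at both higher cutoffs. These shares fell with the cutoff too, to 0.219 and 0.283 at 1.5 and to 0.116 and 0.138 at 2. A test that replaced this one argues against mixing as the whole cause there. In a chromosome 7 run found without the arrays numbered 3, 197 genes lay above the median level. Over these genes this array lay 0.128 of the way to the controls, short of 0.412. The 95% interval of a bootstrap over genes was 0.012 to 0.185, which leaves out the error of a single array. Control-shRNA replicate 3 lay 0.102 of the way in the other direction (0.011 to 0.166). Over all 368 genes of that run the positions were -0.068 and -0.159. Unequal spread of the deposited gene values is argued against as the whole cause. The arrays numbered 3 stayed at 0.417 and 0.307 after quantile normalization, which made the spreads equal. RMA had already normalized by quantiles, so compression that arose before RMA cannot be judged from this. Gene span is argued against as the whole cause too, since both arrays stayed at 0.397 and 0.3 after the span trend was removed. Span did correlate with the deviation of these arrays from their own groups (rho 0.281 and -0.284). A smaller share of mixed RNA stays open for both arrays numbered 3, as do growth state and RNA handling, untested.

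A run of 371 neighbouring chromosome 7 genes, from ZP3 to DYNC2I1, was lower in the arrays labelled TRIB3-shRNA: its median was -0.26, and -0.64 over the 199 genes above the median level, and 34.8% of its genes were called lower (129, with 4 higher) against 5.67% of others (permutation p = 0.00498, the smallest that 200 shuffled orders can give). The span trend is argued against: a search of every other gene without its removal found a run of chromosome 7 too, and there 181 held-out genes had a median of -0.20, and of -0.23 (95% interval -0.37 to -0.12) once the trend was removed. The gradient of the arrays is argued against as the whole cause. Over the run, with the span trend removed, TRIB3-shRNA replicate 3 lay -0.024 of the way from its own group to the controls. This array took part in finding the run, and its deviation from its group itself correlated with span. On the deposited values, over the brighter genes of the run found without this array, the position was 0.128 (0.012 to 0.185). That is short of 0.412 but outside the bound set for this test, so a smaller part of the gradient stays open. A candidate explanation is a difference in DNA copy number between the pools of cells: these held-out genes, with the trend removed, lay below the lowest other run of that length (-0.09). This shows that the change is regional and may have other regional causes, since DNA was not analysed here, and it was found and tested on the same data.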
